A study of Trichoderma reesei with 11 samples.

How the data were processed

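The data were read counts per gene ID for 11 RNA libraries from mycelium of Trichoderma reesei. Groups were taken from the sample labels, which give the strain, the light condition, the growth time of 96 h and the replicate number. Per the labels, RNA was extracted with a plant RNA kit and stranded libraries were made after depletion of ribosomal RNA. The submitters' processing notes name HISAT2 2.2.1, and the series design text names a QM6a transcript set of Li and colleagues. The counting program's version and its settings for strand and for reads with several matches are not given in the sources used here. Reads shared by near-identical or overlapping genes are therefore uncertain.

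The deposited values were raw counts, whole numbers with a different total in each library and no normalization. All 11 columns were matched to samples by the alignment name in the sample descriptions. The table listed 10879 gene IDs, of which 317 had 0 counts in every library. Of these, 10876 were systematic IDs in 7 lettered series with serial numbers, and 3 were mat1-1 rows. The mat1-1 rows held 1 count in all, and QM6a is known to carry the other mating type. None of the IDs matched the gene table of the GCF_000167675.1 assembly (0 of 10879 IDs against 9116 genes), and the file does not pair the IDs with names. The 23 gene lists fixed before the data were examined could therefore not be tested, and the deleted locus was not looked up by its ID. A further mutant strain named in the series design text was not analysed here.

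Gene IDs were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 9040. These held at least 99.96% of the counts of each library. Library sizes were scaled by TMM, and CPM values use the scaled totals. Intervals and floors cover counting error only. A floor is 3 counts over a group, and intervals are at a level of 95%. A floor of 3 counts corresponds to 0.179 to 0.364 CPM in a single library.

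All 11 libraries were fitted in a quasi-likelihood model with a mean for each of the 4 groups and robust estimation, so that the groups shared an estimate of the spread. The groups did not vary alike, so p-values of each comparison also rest on the spread of groups outside it. Contrasts compared the strains in darkness and in light, light with darkness in each strain, and the strain effect in light with that in darkness. P-values were adjusted by the Benjamini-Hochberg method over all tested gene IDs, with a threshold of 0.05, separately in each of 5 comparisons. Numbers changed at least 2-fold use an absolute log2 fold change of 1. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

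Named gene IDs followed a rule written before the data were examined. For IDs without names it takes, in each comparison, the 2 rising and 2 falling gene IDs with the largest log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM in the libraries compared and group ranges that do not overlap. The range condition was not applied to the interaction. Folds against a group at 0 counts are lower bounds. Fitted interaction values that rest on a group at 0 counts or 1 count depend on the prior count and are no bounds.

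The test was run on simulated counts with the real library sizes. Each gene ID had its mean over all libraries and 1 dispersion common to all 4 groups. In these counts, 100 gene IDs changed 2-fold and 100 changed 4-fold (log2 sizes of 1 and 2). The test recovered 59.6% and 85% of them for genotype in darkness over 8879 gene IDs, and 71% and 88% for genotype in light over 8878. For light in the parent it recovered 55% and 77% over 8892, and for light in the deletion strain 60% and 84% over 8903. Between 3 and 10 unchanged gene IDs were called per simulation, 2.04% to 6.49% of the calls. The simulation gave all groups the same spread, as the fit assumes, and the real groups did not vary alike. These rates therefore need not hold for the real libraries.

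Dark libraries and light libraries carry separate runs of library numbers, and the dark libraries were deeper. Light therefore cannot be separated from library batch, while strain comparisons lie within a run and the interaction cancels a shift common to both strains. Alternatives were other scalings, DESeq2 1.42.0, voom in limma 3.58.1, other filters, a fit of only the groups compared, a test against a 2-fold change, a replicate block, removal of the 20 most abundant gene IDs, thinning to 8020351 counts and omission of each library. Numbers of detected gene IDs were compared after thinning each library to 8020351 counts in 10 draws.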

Results

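Gene expression was measured by RNA sequencing in mycelium of Trichoderma reesei, a filamentous fungus that secretes cellulases and is used for enzyme production. The parent strain was QM6a without mus53, a deletion that favours targeted gene replacement. The other strain additionally lacked TR_57513, which the series title names as a kinase of the HOG pathway, the MAP kinase cascade known from yeast for the response to high osmolarity. Both strains were grown on cellulose at 28 °C for 96 h in constant light or in constant darkness. The groups held 2 libraries for the parent in darkness and 3 each for the deletion strain in darkness, the parent in light and the deletion strain in light. Library totals in darkness were 15175573 to 16308391 counts for the parent and 13790024 to 18278047 for the deletion strain. In light they were 8020351 to 8770166 and 8924252 to 10184280. The file does not pair its 10879 gene IDs with gene names, so changes are given by ID and by number.

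The 11 libraries separated by light condition and then by strain. The first principal component of log2 CPM held 60.3% of the variance and parted all 5 dark libraries from all 6 light libraries. The second component held 18.1% and parted the strains within each light condition. Replicates of the deletion strain in light correlated at 0.987 to 0.992 across gene IDs, which are not independent replicates. The range was 0.960 to 0.985 for the parent in light and 0.943 to 0.990 for the deletion strain in darkness, and the 2 parent libraries in darkness correlated at 0.975. Within their groups, deletion replicate 1 in darkness and parent replicate 1 in light had the lowest mean correlation with the other replicates, 0.949 and 0.967. No pair of replicates agreed within sampling noise, since the chi-square per degree of freedom was at least 3.90 in every pair. The chi-square per degree of freedom was 3.90 to 17.8 in the deletion strain in light and 15.3 to 296 in the deletion strain in darkness.

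**Figure D1:**
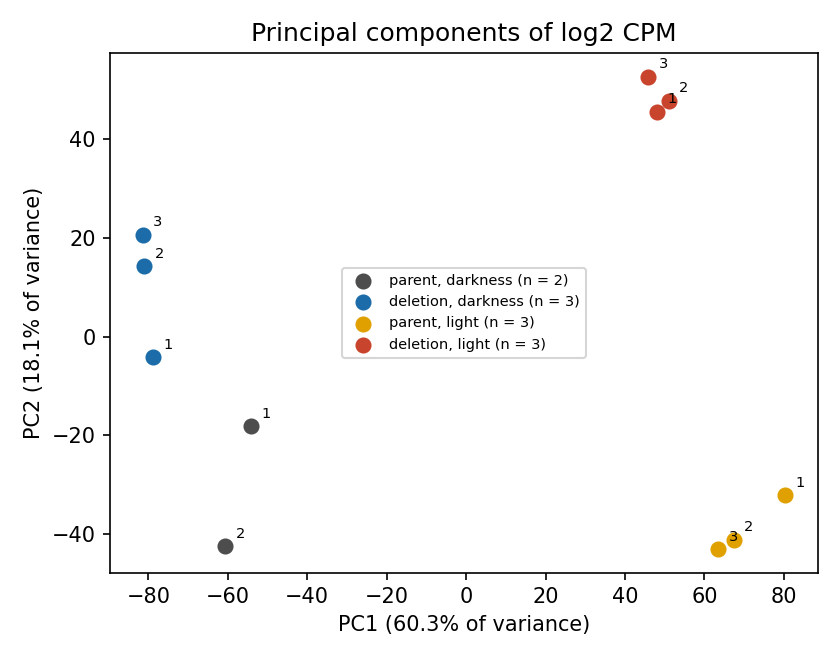
First and second principal components of log2 CPM for the 11 libraries, with points coloured by group and numbered by replicate. The first axis (60.3% of the variance) parts darkness from light and the second (18.1%) parts the strains within each light condition.

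In darkness, loss of TR_57513 was accompanied by higher levels of 655 gene IDs and lower levels of 449, together 1104 of 9040 tested. TrG0050C rose from 2.25 ± 0.34 CPM (SD, n = 2) in the parent to 272.0 ± 77.0 CPM (SD, n = 3), and TrA2130C rose from 0.272 ± 0.073 to 36.4 ± 9.54 CPM. The log2 fold changes were 6.92 (SE 0.77, edgeR adjusted p = 0.00089) and 7.0 (SE 0.65, edgeR adjusted p = 0.000362). TrC0398W fell from 71.0 ± 25.1 to 1.43 ± 0.72 CPM, a log2 fold change of -5.65 (SE 0.48, edgeR adjusted p = 0.000351). TrA1495C had 2758 counts in the 2 parent libraries and 2 counts in the 3 deletion libraries, a ratio of 2409 (95% counting interval 608 to 18131, edgeR adjusted p = 0.0000346).

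Changes of at least 2-fold in darkness were more often increases, with 430 gene IDs rising and 191 falling, or 171 and 116 without parent replicate 1 in darkness, when 205 rose and 184 fell at any size. The direction varied with abundance. Among the 3014 gene IDs of lowest mean level, up to 16.5 CPM, 276 rose and 81 fell. Among the 3013 of highest level, above 70.1 CPM, 150 rose and 227 fell. The CPM ranges of the strains did not overlap for 3872 gene IDs, 42.8% of those tested, where chance gives 20%. With upper-quartile scaling the split was 779 rising and 331 falling. The total was 389 without parent replicate 1 in darkness, 577 without parent replicate 2 in darkness, 695 and 697 without deletion replicates 2 and 3 in darkness, 702 without deletion replicate 2 in light, 238 when only the 5 dark libraries were fitted, and 1708 with DESeq2.

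In light, 1258 gene IDs were higher and 1187 lower in the deletion strain than in the parent, together 2445 of 9040. TrA1495C, at 140.0 ± 6.81 CPM (SD, n = 3) in the parent, had 0 counts in the 3 deletion libraries and was at least 1430-fold lower, against a floor of 3 counts over the group (edgeR adjusted p = 0.0000104). TrA1531C and TrA1529C had 0 counts in the 3 parent libraries. They stood at 18.5 ± 4.51 and 16.9 ± 4.47 CPM in the deletion strain, at least 160-fold and 146-fold higher (edgeR adjusted p = 0.0166 and 0.00969). TrB1722C was lower in the deletion strain, at 0.555 ± 0.046 CPM against 638 ± 583 CPM, and its parent libraries spanned 19.1 to 1176 CPM (edgeR adjusted p = 0.0193).

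At least 2-fold, 622 gene IDs rose and 415 fell in light. Increases prevailed in the class of lowest abundance, with 425 rising and 263 falling, while the class of highest abundance held 456 rising and 501 falling. Ranges did not overlap for 4484 gene IDs, 49.6% of those tested, where chance gives 10%. Scaling by library totals alone gave 1510 rising and 875 falling. The total was 1521 without deletion replicate 2 in light and 1449 without deletion replicate 3 in light, and the TrB1722C change missed the threshold without any one of the deletion libraries in light, with adjusted p up to 0.0745 in edgeR. With voom, TrA1531C, TrA1529C and TrB1722C missed the threshold (limma adjusted p = 0.326, 0.178 and 0.582, the highest among their alternatives). TrA1531C and TrB1722C also missed it in the test against a 2-fold change.

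**Figure D2:**
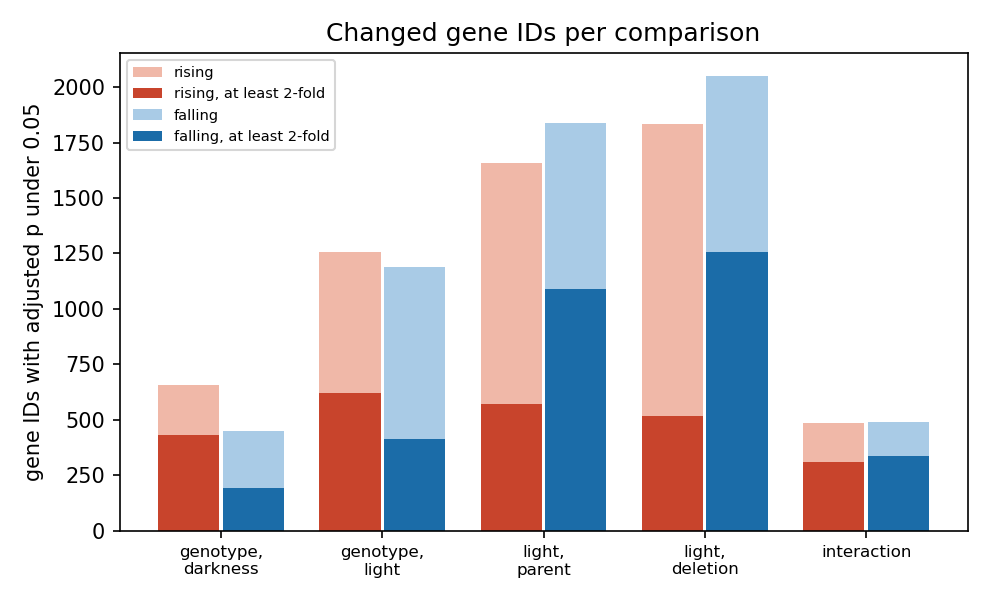
Number of gene IDs with an edgeR adjusted p under 0.05 in each comparison, rising and falling, with the part that changed at least 2-fold in the darker shade. Between the strains, 1104 gene IDs differed in darkness and 2445 in light. Between light and darkness, 3498 differed in the parent and 3884 in the deletion strain, where light and library batch cannot be told apart.

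The genotype effects in light and in darkness overlapped in part. Of the gene IDs that passed in each condition, 262 rose in both, where independent lists would share 91.1, and 161 fell in both, where 59.0 would be shared. Opposite changes were found for 70 gene IDs, with 148.5 for independent lists. Across the 9040 gene IDs, which are not independent replicates, the log2 fold changes of the comparisons correlated at Pearson r = 0.30 and Spearman rho = 0.28. The comparisons share no library, but both take their spread from the same fit. The lists of passing gene IDs are therefore not independent, and the numbers for independent lists are only a rough benchmark. The Pearson r was 0.16 without parent replicate 2 in darkness.

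The genotype effect differed between light and darkness for 975 gene IDs by the interaction test, 485 with a more positive and 490 with a more negative effect in light. Of these, 613 passed the genotype test in light and not in darkness, 214 in darkness and not in light, 44 in both with the same direction, 70 in both with opposite directions and 34 in neither. TrA1904W stood at 74.2 ± 0.90 CPM (SD, n = 2) in the parent and 54.3 ± 22.3 CPM (SD, n = 3) in the deletion strain in darkness. In light it had 0 counts in the parent and 5.90 ± 0.84 CPM in the deletion strain (edgeR adjusted p = 0.0035 for the interaction). TrC1547W was likewise at 0 counts in the parent in light and at 1.56 ± 1.54 CPM in the deletion strain, against 34.9 ± 27.7 and 3.39 ± 1.58 CPM in darkness (edgeR adjusted p = 0.0247).

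TrA0074C and TrC1527C showed the opposite interaction. TrA0074C reached 55.1 ± 36.0 CPM (SD, n = 3) in the parent in light and stayed at 0.451 ± 0.214 CPM in the deletion strain, with 0.313 ± 0.076 and 1.34 ± 0.93 CPM in darkness (log2 interaction -8.96, SE 1.29, edgeR adjusted p = 0.00381). TrC1527C reached 41.9 ± 34.7 CPM in the parent in light and 0.593 ± 0.586 CPM in the deletion strain (edgeR adjusted p = 0.0117). The interaction total was 386 without parent replicate 1 in darkness, 595 without parent replicate 2 in light, 617, 552 and 549 without deletion replicates 1, 2 and 3 in light, and 1532 with DESeq2. The TrC1547W interaction missed the threshold without parent replicate 1 in darkness, deletion replicate 3 in darkness or deletion replicate 3 in light, and the TrC1527C interaction without parent replicate 1 in darkness, with edgeR adjusted p up to 0.0597 and 0.073. With voom, all 4 of these interactions missed the threshold, at limma adjusted p = 0.0513 for TrA1904W, 0.122 for TrC1547W, 0.14 for TrA0074C and 0.259 for TrC1527C. The TrC1547W interaction missed it in 7 of 23 alternatives in all, among them the test against a 2-fold change.

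**Figure D3:**
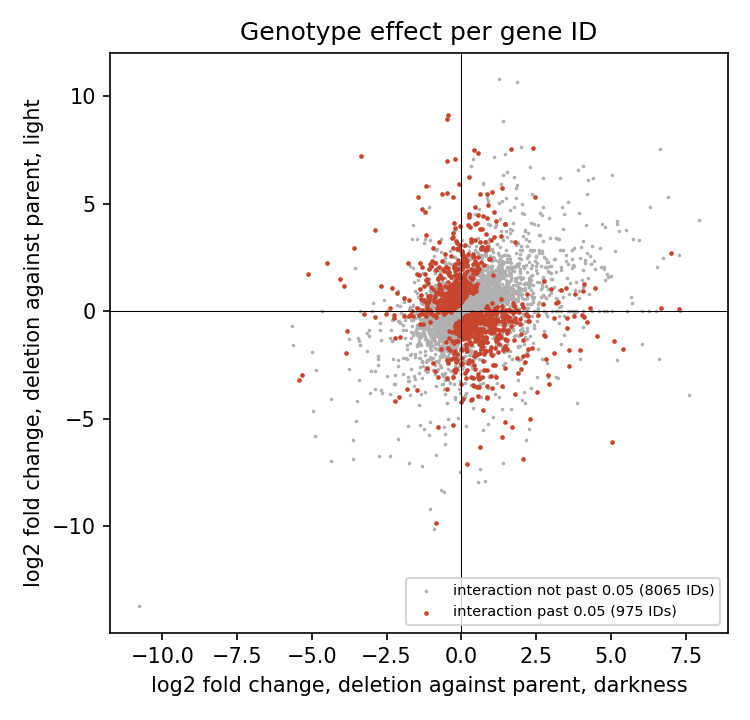
Log2 fold change of the deletion strain against the parent in darkness (x axis) and in light (y axis), 1 point per tested gene ID, with the 975 gene IDs past the interaction threshold in red. The effects correlate at Pearson r = 0.30, and TrA1495C is the point at the lower left.

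In the parent, 1657 gene IDs were higher and 1841 lower in light than in darkness, together 3498 of 9040. At least 2-fold, 570 rose and 1092 fell. TrG1206C went from 4334 ± 1081 CPM (SD, n = 2) in darkness to 1 count in 3 light libraries, and TrB0435C from 918 ± 277 CPM to 0 counts, at least 7962-fold lower (edgeR adjusted p = 0.0000494 and 0.000502). TrC1527C rose from 1 count in the dark libraries to 41.9 ± 34.7 CPM (edgeR adjusted p = 0.00217). TrG0196W had 0 counts in darkness and 17.1 ± 17.2 CPM in light, with a range of 0.338 to 34.7 CPM (edgeR adjusted p = 0.0346). The TrG0196W change missed the threshold in 9 of 24 alternatives. Among them were the test against a 2-fold change and the fit of only the groups compared.

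Ranges of the parent libraries in light and darkness did not overlap for 5465 gene IDs, 60.5% of those tested, where chance gives 20%. Libraries from darkness and from light carry separate runs of library numbers in the labels, so light and library batch cannot be told apart, and with upper-quartile scaling the split was 2167 rising and 1563 falling, with library totals alone 2461 and 1433. The number of rising gene IDs was 1010 without parent replicate 1 in darkness and 1091 without parent replicate 2 in darkness. The TrG0196W change missed the threshold when any of 6 libraries was left out, namely either parent library in darkness, parent replicates 2 or 3 in light, or deletion replicates 2 or 3 in light, with edgeR adjusted p up to 0.134, and with voom TrG0196W, TrC1527C and TrB0435C missed it (limma adjusted p = 0.269, 0.158 and 0.0519).

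In the deletion strain, 1832 gene IDs were higher and 2052 lower in light, together 3884 of 9040, and 518 rose and 1255 fell at least 2-fold. TrE0645C rose from 0.251 ± 0.182 to 200.6 ± 23.8 CPM (SD, n = 3 each), a log2 fold change of 9.53 (SE 0.29, edgeR adjusted p = 1.34e-07). TrD1308C rose from 4.53 ± 1.09 to 689 ± 10.2 CPM, a log2 fold change of 7.25 (SE 0.37, edgeR adjusted p = 2.12e-06). Both also rose in the parent, to 45.3 ± 4.35 and 239 ± 78.8 CPM in light. TrA2144C and TrE0661W, at 183 ± 127 and 179 ± 291 CPM in darkness, had 0 counts in the 3 light libraries and were at least 1872-fold and 1825-fold lower (edgeR adjusted p = 0.00258 and 0.0411). The bound for TrE0661W rests on deletion replicate 1 in darkness and is 107-fold without it.

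Ranges did not overlap for 5406 gene IDs, 59.8% of those tested, where chance gives 10%. The same confounding of light and library batch applies, and scaling by library totals alone gave 3116 rising and 1558 falling. TrE0661W spanned 10.5 to 515 CPM in darkness and missed the threshold when either parent library in darkness or any deletion library in light was left out, with edgeR adjusted p up to 0.0816. With voom, TrA2144C and TrE0661W missed the threshold (limma adjusted p = 0.0701 and 0.381). TrE0661W missed it in 9 of 23 alternatives in all, among them the test against a 2-fold change and the fit of only the groups compared. An alternative that gave no fold change or no adjusted p for TrE0661W is not among the 23.

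The light responses of the strains overlapped. In both strains 934 gene IDs rose, where independent lists would share 335.8, and 1140 fell, where 417.9 would be shared. Opposite changes passed for 126 gene IDs, with 749.2 for independent lists. The log2 fold changes correlated across gene IDs at Pearson r = 0.74 and Spearman rho = 0.60. Among the 970 gene IDs that passed the interaction test and a light test in at least 1 strain, the light effect was larger in the parent for 568 and in the deletion strain for 402. A batch that shifted both strains alike would add to the overlap of the light responses. Here too both lists take their spread from the same fit and are not independent.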

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

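The comparisons with the SD between fits and within the same fit, and the joint omission of 2 libraries, were chosen only after the result was seen. The genotype effect differed between light and darkness for 975 gene IDs, by the interaction test in edgeR. The log2 interaction was -4.30 for TrA2130C (adjusted p = 0.0477), -11.10 for TrC1527C (adjusted p = 0.0117) and -8.96 for TrA0074C (adjusted p = 0.00381). For TrC1547W and TrA1904W the fitted values were 10.57 (adjusted p = 0.0247) and 9.60 (adjusted p = 0.0035). Both depend on the prior count and are no bounds, because the parent in light had 0 counts, and the value for TrC1527C depends on it because the parent in darkness had 1 count.

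More gene IDs passed the genotype test in light (2445) than in darkness (1104). Both numbers rest on an estimate of the spread shared by groups that did not vary alike. With only the groups compared in the fit, 2936 passed in light and 238 in darkness. At equal depth the light number was 2.44 times the dark number. The dark libraries were the deeper ones, so depth would favour calls in darkness. Thinning them could not lower the ratio by removing a depth advantage of light, and no conclusion is drawn from it. Without deletion replicate 1 in darkness, which lies apart from its group, 1426 gene IDs passed in darkness and 3055 in light. This ratio of 2.14 lies above 1.5 by slightly more than the SD of 0.602 between the ratios of the 3 fits without a dark deletion library. These fits share most libraries and include the ratio under test. Their SD is no sampling error, and no conclusion about that library is drawn from it. Set against the light number of all 11 libraries divided by 1.5, or 1630, the 1426 falls short by less than the SD of 421 between the dark numbers of those fits. With parent replicate 1 in light also left out, the numbers were 1916 in darkness and 2915 in light, a ratio of 1.52. It was 1.59 with parent replicate 1 in light alone left out, so the lower ratio does not single out deletion replicate 1. A share of either library in the difference stays open. With only a parent library in light left out, the light number fell to 1662, against a bound of 1656 and an SD of 178 between such fits, and in the 3 such fits the light number was 1.59, 2.04 and 1.82 times the dark number of the same fit. The lowest, 1.59, lies above 1.5 by less than the SD of 0.226 between the fits. That SD, too, is no sampling error, since these fits share most libraries and include the ratio under test. No conclusion is drawn from it. Whether the smaller parent group in darkness accounts for the difference, or a genotype effect that depends on light, stays open. In light, the real grouping gave 2445 gene IDs and the highest of the other splits gave 0. The 10 splits of 6 libraries, of which 1 gave as many, are too few for a share under 0.05. The same holds for light in the deletion strain, with 3884 gene IDs in the real grouping, 0 in the highest other split and 1 of 10 splits giving as many.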

How the results depend on the processing

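The joint omission of deletion replicate 1 in darkness and parent replicate 1 in light, the omission of single libraries for the correlation of genotype effects, and the alternatives for detected gene IDs were chosen after seeing the data; the others were fixed before the data were examined. All 23 gene lists and their alternatives were not run, since no ID could be matched. DESeq2 called 1708 gene IDs for genotype in darkness and 1532 for the interaction, with no other total moved by over 1.5 times. Fitting only the groups compared gave 238 for genotype in darkness and 2936 for genotype in light. The test against a 2-fold change, stricter by construction, gave 98, 365, 834, 949 and 177 for genotype in darkness, genotype in light, light in the parent, light in the deletion strain and the interaction. Joint omission of deletion replicate 1 in darkness and parent replicate 1 in light gave 1916 for genotype in darkness. The cause was not tested except where construction is named. Other scalings and filters, voom, removal of the 20 most abundant gene IDs and thinning kept every total within 1.5 times. Library totals alone moved the median log2 fold change of all gene IDs by 0.15 for light in the parent and by 0.20 for light in the deletion strain, and upper-quartile scaling by 0.10 in the parent, so the balance of rising and falling gene IDs in light is relative to the scaling.

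Leaving out single libraries gave 389 to 1426 gene IDs for genotype in darkness, 1449 to 3055 for genotype in light, 2368 to 4035 for light in the parent, 2869 to 4034 for light in the deletion strain and 386 to 1175 for the interaction. The correlation of genotype effects ranged from 0.16 to 0.37. A group left with 1 library is assumed to vary like the others. The 20 named results were each checked in 23 or 24 alternatives, 474 checks in all. Alternatives that gave no result for a gene ID are not counted. They kept direction in all 474 checks and their side of the threshold in 434. Of the 40 that lost it, 12 were under voom, and TrG0196W and TrE0661W lost it most often, in 9 alternatives each. TrA1495C passed in all alternatives of both strain comparisons.

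Replicate numbers are shared between groups but did not pair the libraries by the rule that every pair correlates above 0.1. Deviations of same-numbered libraries in light correlated at 0.16, 0.0040 and 0.16, and in darkness at -0.38 and -0.23. Those of differently numbered libraries correlated at -0.17 to 0.054 in light, below the values of 0.16, and at -0.38 to 0.38 in darkness. A partial pairing in light is therefore not excluded. Between darkness and light the correlations were 0.26 and 0.14 in the parent, with 2 pairs, and 0.015, -0.052 and -0.017 in the deletion strain. With the replicate number as a block, 157 gene IDs passed for genotype in darkness, 1209 for genotype in light, 2824 for light in the parent, 3607 for light in the deletion strain and 716 for the interaction. Not every light library correlated best with its own number.

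Depth limits low levels, since 3 counts correspond to up to 0.364 CPM in the shallowest library. The detected-ID difference between strains stayed positive under each alternative, at 204.7 to 270.8 gene IDs.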

Other observations

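The tests of read carry-over, of sample mislabelling and of the identity of TrA1495C were chosen only after the result was seen. More gene IDs were detected in the deletion strain than in the parent. After thinning every library to 8020351 counts, 9817 ± 17.0 gene IDs (SD, n = 3) had reads in the deletion strain in darkness and 9570 ± 20.5 (SD, n = 2) in the parent. In light the numbers were 9568 ± 16.3 and 9300 ± 52.9 (SD, n = 3 each). The exact two-sided permutation p was 0.1 in each condition, the smallest that the design allows.

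A related pattern concerned gene IDs well expressed in darkness, with at least 10 CPM in all 5 dark libraries. In 10 draws at equal depth, 18 to 20 of them had 0 counts in all 3 parent libraries in light, and 2 to 4 in all 3 deletion libraries in light. These draws reuse the same libraries and are not replicates. A biological difference between the strains stays open and was not tested. Sequencing depth is argued against, because the lowest deletion library exceeded the highest parent library by at least 196.3 gene IDs at equal depth. Abundant gene IDs taking the parent's reads are also argued against, since the gap was 187.5 with the 20 most abundant removed. Reads carried over from a single dark library would keep its proportions over these 18 to 20 gene IDs, but the lowest chi-square per degree of freedom was 63.5. This argues against a single dark source for all of these reads. Carry-over from mixed sources or into only some of these gene IDs stays open. The other detected gene IDs were not covered by this test.

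TrA1495C was the only gene ID with at most 2 counts in every deletion library and at least 100 in every parent library (1 such ID), and 0 gene IDs showed the reverse. It may be the deleted locus, a hypothesis that the file cannot settle because the IDs carry no names. A mislabelled library is argued against by the other tested gene IDs, since every library correlated better with its own group than with the other strain in the same light. The smallest difference in mean correlation was 0.021, for deletion replicate 1 in darkness, about equal to the SD of 0.0209 between replicate correlations in darkness, so the margin is narrow for that library.

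Serial numbers within the 7 ID series may follow gene order, a hypothesis tested here without coordinates. Genotype effects of consecutive serial numbers correlated at 0.195 in darkness and 0.211 in light, above every one of 1000 shuffled orders (highest 0.045 and 0.034). The permutation p of 0.001 is the smallest these can give. Reads counted for an adjacent ID would not reach gene IDs 3 numbers apart. There the correlation was 0.070 in darkness, above every shuffled order, but 0.036 in light, within the shuffled range of up to 0.043. The highest shuffled value is a strict bound, so a weak correlation at that distance in light is not excluded. Counting for an adjacent ID alone would not give the value in darkness. It could still add to the higher correlation of consecutive numbers there. That explanation therefore stays open in light, and as a part of the pattern in darkness.

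Runs of at least 4 consecutive gene IDs changed at least 2-fold the same way. There were 2 such runs in darkness and 7 in light for genotype, where shuffled orders gave means of 0.030 and 0.15. The longest in light was TrE numbers 10 to 15, which fell with a median log2 fold change of -3.05, and TrA numbers 1529 to 1533 rose, for which no median is given because the parent in light had 0 counts for some of them. In darkness TrG numbers 816 to 819 and 821 to 824 rose, with medians of 3.89 and 5.47. Light gave 27 runs in the parent and 31 in the deletion strain, against means of 1.29 and 2.03. These runs were chosen after their values were seen.

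Rising gene IDs in darkness were more frequent near the ends of the series. Within the outer 5% at either end, 12.8% of 827 gene IDs rose in the deletion strain, against 6.68% elsewhere. The p from 10000 circular shifts was 0.0001, the smallest they can give. The shifts move gene IDs and do not measure the spread between libraries. Other fits were not tested for this pattern, and the fit of only the dark libraries had 165 rising gene IDs, against 655 with all libraries. Outer gene IDs might rise more often because they are less abundant, but the share was higher in each of 3 abundance classes and the abundance-matched p was 0.0002. In light the shares were 16.2% and 13.7% with a permutation p of 0.069, inside the middle 90% of the shifts, which does not show that the ends were alike. The abundance-matched p was 0.054, with outer and inner shares of 12.3% and 14.4% in the class of lowest abundance, 19.8% and 11.9% in the middle class and 23.7% and 14.7% in the highest. Whether the series ends are chromosome ends was not tested.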
